A study of Dictyostelium discoideum with 24 samples.

How the data were processed

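RNA was measured in amoebae of Dictyostelium discoideum, a soil amoeba used as a model of motility, phagocytosis and development, in the axenic strain AX3. Wild type cells and cells with the ttpA-C240ins insertion were grown on the surface of flasks to about 80% confluence or in liquid to about 2 M cells per ml, with 6 libraries in each of the 4 groups. Per the labels' protocols, total RNA was purified with a spin column kit, and 250 ng of each sample went into an Illumina TruSeq RNA library with 12 PCR cycles. The design text speaks of 6 cultures per genotype, and the labels do not say whether the surface and liquid libraries of a genotype came from separate cultures or days. P-values therefore measure the spread between these libraries, which may be partly technical.

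The authors deposited a table of whole-number read counts per gene, made with bcl2fastq, STAR 2.6.0c and featureCounts 1.5.1 per the submitters' processing notes. The genome build, the annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes were not told apart. The second deposited table holds a signal per gene, which is the count divided by 1 size factor per sample, as the constant ratio between the deposited tables shows. Gene model lengths are a multiple of 3 in 94.8% of genes, as coding lengths would be, and what the lengths of the other genes cover is not known. The headers of the mutant columns name the allele R225ins while the sample titles name it C240ins; columns were matched to samples by growth form and sample number, and the name of the titles is used here.

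No gene in the count table carries the name ttpA, so the level of the mutated gene was not analysed here and the genotype labels were not checked through it. A reference table of assembly dicty_2.7, which may differ from the build of the authors, was used for the order of neighbouring genes, and 12728 of the 12865 gene IDs (98.9%) matched it. A search for a sequence motif downstream of stop codons was planned and was not run, because no genome sequence was used here.

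From the counts, genes were filtered with filterByExpr and scaled with TMM factors in edgeR 4.0.16 (R 4.3.3), which left 10116 of 12865 genes. All 24 libraries entered 1 quasi-likelihood fit (glmQLFit and glmQLFTest, robust) with 1 coefficient per group, and 5 contrasts were taken: mutant against wild type in each growth form, liquid against surface growth in each genotype, and the interaction of both factors. P-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, with a threshold of 0.05, and genes that also changed at least 2-fold were counted apart. Levels are CPM, the counts of a gene relative to the library total scaled by the TMM factor, given as mean ± SD over 6 libraries. Standard errors of log2 fold changes are the fitted change divided by the square root of the F statistic. Depth ran from 42.7 to 102.3 M counts per library, where M is mega, and the common biological coefficient of variation was 7.64%, so small changes pass the test.

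Before the data were examined, 32 gene lists were fixed from general knowledge, and 31 of them had at least 3 tested members. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. With an estimated correlation 3 of the 48 list calls held, namely the vacuolar proton pump in both genotypes and lysosomal enzymes in the mutant, all for liquid against surface growth.

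The genes named in the text follow a rule fixed before the data were examined. In each pairwise comparison it takes the 8 largest increases and 8 largest decreases among genes with a name, an adjusted p under 0.05, a mean CPM of at least 10 in the higher group and no overlap of the CPM of the 6 against 6 libraries, and 2 and 2 among genes with an ID only. For the interaction it takes 5 positive and 5 negative genes, and in each described list up to 4 members with the largest fold among those that passed. Genes named outside the rule are said to be so. The actins, the cup, uduA and cysteine protease genes and transposable elements belong to families with similar copies that may share reads, so their values are uncertain. Sharing of reads was not examined here.

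Alternatives fixed before the data were examined were edgeR with relative log expression factors, DESeq2 1.42.0, no filter, a mean CPM of at least 5, the replicate number as a block, limma on log2 of the deposited normalized signal plus 1 or plus 10, and fits of the 2 compared groups only. Chosen after seeing the data were scaling by total counts, leaving out 141 genes in stretches of neighbouring genes that differed between the lines, and leaving out, 1 at a time, wild type liquid replicate 3, wild type surface replicates 1 and 2 and mutant surface replicate 6, and leaving out replicate 1 of every group. The paired libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.09 to 99.4 over 8690 genes and 60 pairs, so no library was counted as deposited in duplicate. The procedures were tested on simulated counts of 10116 genes with 200 planted changes: a 2-fold change was recovered in 95.5% of planted genes for mutant against wild type in surface and in liquid growth, 92.4% for liquid against surface growth in the wild type, 93.9% in the mutant, and 89.4% for the interaction. A 1.25-fold change was recovered in 53.7% of planted genes for mutant against wild type in surface growth and in 44.8% for the interaction, where a 1.5-fold change was recovered in 59.7%. False calls made up 2.61% (wild type growth) to 6.02% (surface genotype) of the calls. Genes were drawn independently, without deviations shared between libraries.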

Results

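The transcriptomes of wild type and ttpA-C240ins amoebae were compared in surface and in liquid growth, to find which transcripts differ between these lines. In the mutant, ttpA, the tristetraprolin family gene of this organism, carries an insertion. Proteins of that family bind and destabilise mRNAs in animals. The level of ttpA itself was not analysed here, because no gene in the count table carries its name. The titles give the same allele name for all mutant libraries. Other differences between the lines therefore cannot be told apart from the insertion. The 24 libraries held 71.5 ± 12.4 M counts (SD, n = 6) in wild type surface, 68.0 ± 9.13 in wild type liquid, 79.9 ± 12.2 in mutant surface and 75.3 ± 23.1 in mutant liquid cultures. The first principal component held 40.5% of the variance and set wild type surface libraries (mean -43.3) apart from mutant surface (1.10), wild type liquid (18.6) and mutant liquid libraries (23.6). Transcripts of cytosolic ribosomal proteins took 21.2% ± 0.531 of the counts in wild type surface, 22.3% ± 0.837 in mutant surface, 27.0% ± 1.04 in wild type liquid and 22.9% ± 0.760 in mutant liquid cultures (SD, n = 6).

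**Figure D1:**
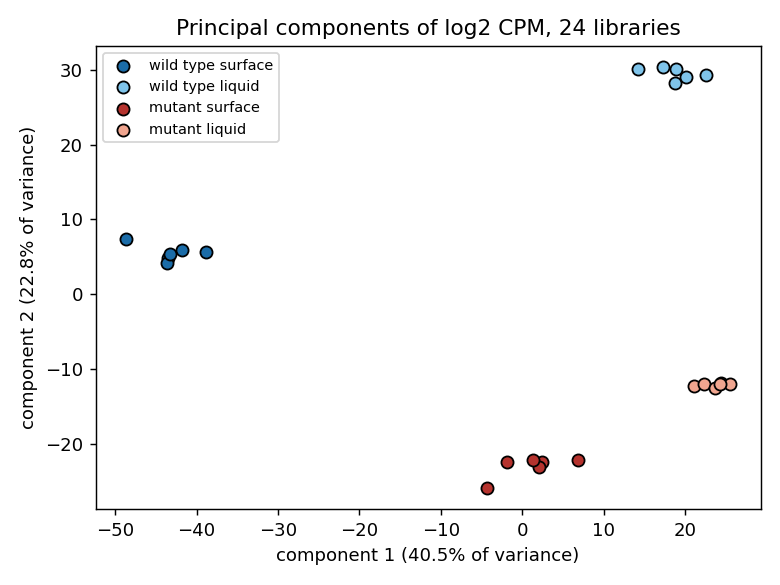
Principal components 1 and 2 of log2 CPM over 10116 genes, 1 point per library and 1 colour per group of 6. The first axis (40.5% of the variance) parts the wild type surface libraries, with a mean of -43.3, from the others.

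The scaling between libraries sets how many genes lie on each side of 0. With total-count scaling in place of TMM the median log2 change of all genes became -0.30 for mutant against wild type in surface growth, 0.19 in liquid growth, -0.42 for liquid against surface growth in the wild type, 0.08 in the mutant and 0.50 for the interaction. With TMM those medians were -0.04, 0.01, -0.05, 0.01 and 0.06. Changes below are relative to the TMM scale.

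In surface growth the mutant had 4.57-fold more DD3-3 (DDB_G0283095) RNA (3318 ± 227 CPM in wild type, 15153 ± 1251 in mutant; SD, n = 6) and 4.02-fold more sodC (DDB_G0282993) RNA, which encodes a superoxide dismutase (1511 ± 68.3 against 6072 ± 186). The dduF transcript rose 4.02-fold, and the calcium up-regulated genes cupI, cupC, cupF, cupH and cupB rose 4.69-, 3.89-, 3.67-, 2.92- and 2.56-fold. Among named genes that met the rule, the largest decreases were in cprA (DDB_G0290957), a cysteine protease gene that fell from 68.2 ± 4.55 to 0.496 ± 0.112 CPM, and prsB (DDB_G0272246), a ribose-phosphate pyrophosphokinase gene that was 128-fold lower at 0.168 ± 0.0610 CPM. Transcripts of uduA2, uduA3 and uduB were 6.69-, 5.95- and 5.27-fold lower in the mutant, and dia2, celB and symA were 7.61-, 5.30- and 4.91-fold lower. Among genes without a name, DDB_G0279275 and DDB_G0270058 rose 7.88- and 7.48-fold, and DDB_G0290971 and DDB_G0290967 fell to 0.139 and 0.226 CPM from 20.4 and 30.8 CPM. Both of the latter lie close to cprA in the gene order, and neighbours of prsB were lower too. These decreases may thus not be separate changes, and loss of the genes from the mutant line was not measured. The rule for named genes required that the CPM of the 6 mutant and the 6 wild type libraries not overlap. That separation, in each gene of this paragraph, is therefore no further evidence. The highest adjusted p among them was 3.3e-11.

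Of 20 genes on the substrate adhesion list, 17 rose and 0 fell in the mutant in surface growth, among them csbA (log2 change 1.35, SE 0.062), csbB (0.82) and the myosin VII gene myoI (0.72). The list's adjusted p was 1.0e-05, and 0.66 with an estimated correlation. The genes csbA and csbB were also put on the aggregation and cAMP signalling list, so their changes are not evidence on substrate adhesion in particular. Of 57 genes of actin-binding and motility proteins, 43 rose and 5 fell, with the profilin genes proC (2.37-fold) and proA (1.95-fold) and the alpha-actinin gene abpA (1.81-fold) among the largest increases (adjusted p = 6.4e-10; adjusted p = 0.66 with an estimated correlation). The gene proC lies in a stretch of neighbouring genes of which 96 of 98 were higher in the mutant in both growth forms. Of 13 glycolysis and glycogen genes, 12 rose, including glpD (1.22) and gpdA (0.57), with an adjusted p of 0.00024, and an adjusted p of 0.86 with an estimated correlation. Of 80 cytosolic ribosomal protein genes 69 rose, with a median log2 change of 0.29 that was 0.03 under total-count scaling (adjusted p = 1.4e-05; adjusted p = 0.87 with an estimated correlation). The genes rpl32 (2.45-fold), rpl27 (2.37-fold) and rps25 (2.32-fold) were among the largest increases. Of these, rpl27 and rps25 lie in the stretch that holds proC. The gene rpl32 lies at the uneven start of a further stretch of 11 genes, between rpb10 (-0.50) and rabR (2.51; both named outside the rule). Of 198 transposable element genes 96 fell and 25 rose (adjusted p = 0.00024; adjusted p = 0.55 with an estimated correlation, and adjusted p = 0.24 with total-count scaling), and DDB_G0305714_RTE went from 41.9 ± 1.14 to 2.00 ± 0.17 CPM. Of 32 actins with near-identical copies 22 rose, such as act21 (1.23), and 8 fell, such as act1 (-1.68), with an adjusted p of the list of 0.031, and adjusted p = 0.87 with an estimated correlation. Adjusted over the list alone, 17 adhesion genes rose and 1 fell, 44 and 5 motility genes, 12 and 0 glycolysis genes, 72 and 0 ribosomal protein genes, 25 and 96 transposable elements, and 23 and 8 actins.

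Of 31 lists 11 passed, 10 of them upward. Those not described above were proteasome (adjusted p = 0.00011), aminoacyl-tRNA synthetase (0.0013), mitochondrial respiration (0.0074), DNA replication (0.026, and adjusted p = 0.089 with total-count scaling) and heat shock protein genes (0.028), whose adjusted p with an estimated correlation was 0.50, 0.87, 0.86, 0.86 and 0.86. They had medians of 0.22 to 0.27 and, for the proteasome, DNA replication, respiration and heat shock lists, of -0.05 to -0.02 under total-count scaling. In total 6224 of 10116 genes passed, 2929 higher and 3295 lower in the mutant, and 185 and 501 of these differed at least 2-fold (686 in all, and 194 when a mean CPM of at least 5 was required). With total-count scaling the split was 1023 higher and 6352 lower.

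In liquid growth cinC (DDB_G0287685) RNA rose 9.35-fold in the mutant, from 27.4 ± 3.16 to 255 ± 10.8 CPM (SD, n = 6). DD3-3 and sodC rose 6.70- and 6.37-fold, in the direction seen in surface growth. Transcripts of iliC rose 5.75-fold, comD 4.06-fold, pdiA, which encodes a secreted inhibitor of the cAMP phosphodiesterase, 3.99-fold, the ABC transporter gene abcC6 3.22-fold and uduC 3.12-fold. As in surface growth, prsB (24.2 to 0.206 CPM) and cprA (40.8 to 0.504 CPM) were nearly absent from the mutant, as were 8 other genes, and uduA3, uduA2 and uduB fell 7.86-, 7.61- and 4.92-fold. The countin family gene ctnC fell 5.46-fold, uduA1 4.43-fold and act1 3.43-fold. Among genes without a name, DDB_G0267306_RTE and DDB_G0284277 rose 23.4- and 14.8-fold, and DDB_G0267194 fell from 18.2 to 0.162 CPM. Neighbours of DDB_G0267194, prsB and cprA were lower too, and gene loss was not measured. The libraries of the mutant and the wild type did not overlap for any gene named in this paragraph, which the rule required. The highest adjusted p, in uduA1, was 2.1e-08.

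**Figure D2:**
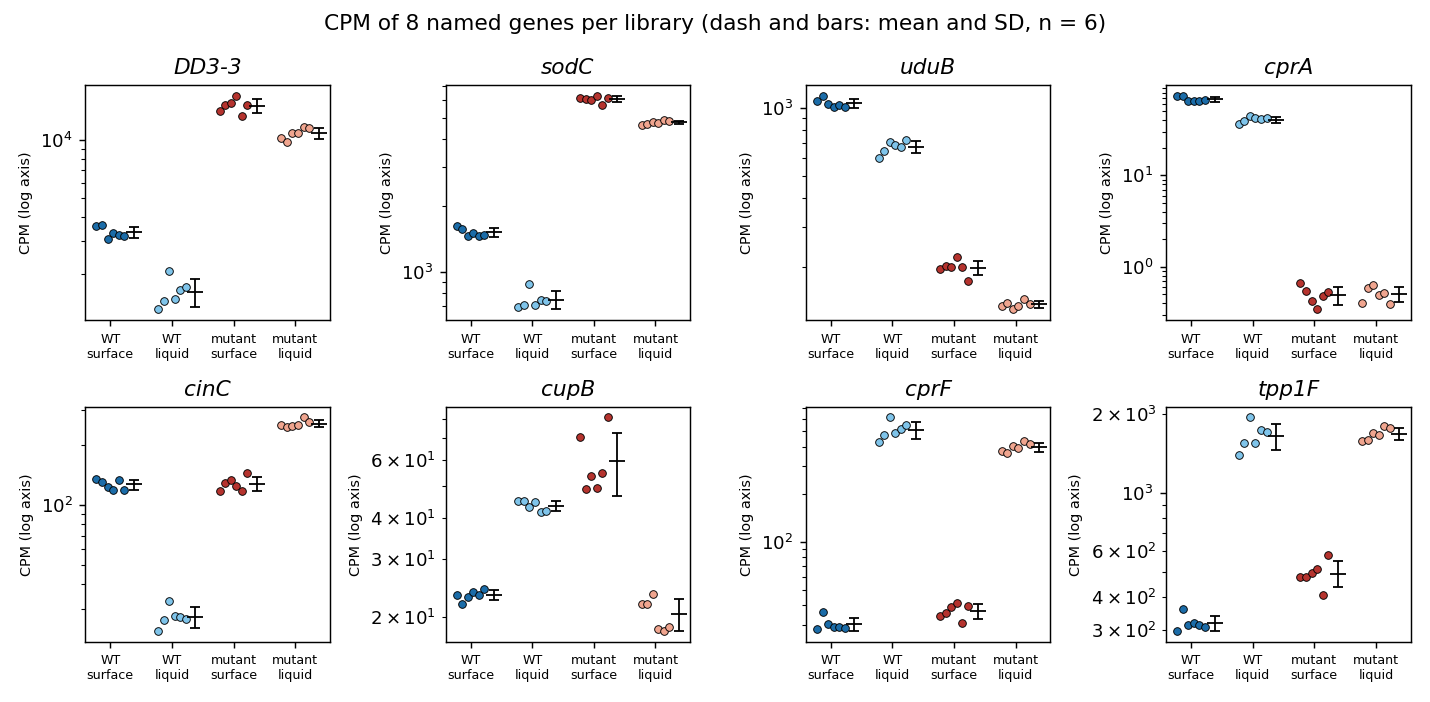
CPM of 8 named genes in each library on a log axis, in the 4 groups of 6, with the mean and SD beside the points. DD3-3 and sodC are higher and uduB and cprA lower in the mutant in both growth forms, while cupB is higher in mutant surface (59.7 CPM) than wild type surface cultures (23.3 CPM) and lower in mutant liquid (20.4 CPM) than wild type liquid cultures (43.5 CPM).

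Of 80 cytosolic ribosomal protein genes 72 fell and 3 rose in the mutant in liquid, with a median log2 change of -0.47 (-0.28 under total-count scaling) and examples rpl14 (-0.61) and rpl28 (-0.59). The adjusted p was 8.6e-12, and the adjusted p with an estimated correlation was 0.99. Of 33 ribosome biogenesis genes 29 fell, such as bms1l (-0.47) and rrs1 (-0.43), while utp18 rose (0.68; it lies in the stretch that was higher in the mutant), with adjusted p = 0.00010 and an adjusted p of 0.99 with an estimated correlation. Of 37 proteasome genes 23 rose and 0 fell, including psmD6 (0.43) and psmD12 (0.34), with adjusted p = 0.013, and adjusted p = 0.99 with an estimated correlation. Of 32 lysosomal enzyme genes 14 fell, such as alyA (-0.65) and alyC (-0.63), which encode lysozymes, and 8 rose, such as nagD (1.26); the adjusted p was 0.015, and the adjusted p with an estimated correlation was 0.99. The median of the lysosomal genes was -0.16, and 0.01 under total-count scaling. Adjusted over the list alone, 3 ribosomal protein genes rose and 73 fell, 1 and 29 ribosome biogenesis genes, 27 and 1 proteasome genes, and 8 and 14 lysosomal enzyme genes. In all, 4141 genes passed, 2081 higher and 2060 lower in the mutant, and 393 and 147 of these differed at least 2-fold (540 in all, and 168 when a mean CPM of at least 5 was required). With total-count scaling the split was 4475 higher and 855 lower.

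The genotype differences of the growth forms overlapped in part. Of 2839 genes that passed in both, 757 were higher and 735 lower in the mutant in both, where independent lists would share 603 and 671. At least 96 of the 757 lie in the stretch of neighbouring genes that holds proC. The excess of genes higher in both thus rests in part on 1 region. The other 1347 differed in opposite directions: 735 were higher on the surface and lower in liquid, and 612 the reverse, where independent lists would share 596 and 678. The log2 changes had a Pearson correlation of 0.26 and a Spearman correlation of 0.02 across genes, which are not independent replicates. The stretch that holds proC, rps25, rpl27 and utp18 begins at a chromosome end and runs from DDB_G0294292 to DDB_G0271162 (limits named outside the rule). Its 98 genes with a mean CPM of at least 1 had median log2 changes of 0.96 in surface and 1.05 in liquid growth (10th to 90th percentile 0.67 to 1.27 and 0.74 to 1.34), while the next 40 genes had medians of -0.15 and -0.03. Counted apart from these, over all 119 tested genes within the limits of the stretch whatever their CPM, it held 52.4% of the 187 genes at least 1.5-fold higher in the mutant in both growth forms.

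**Figure D3:**
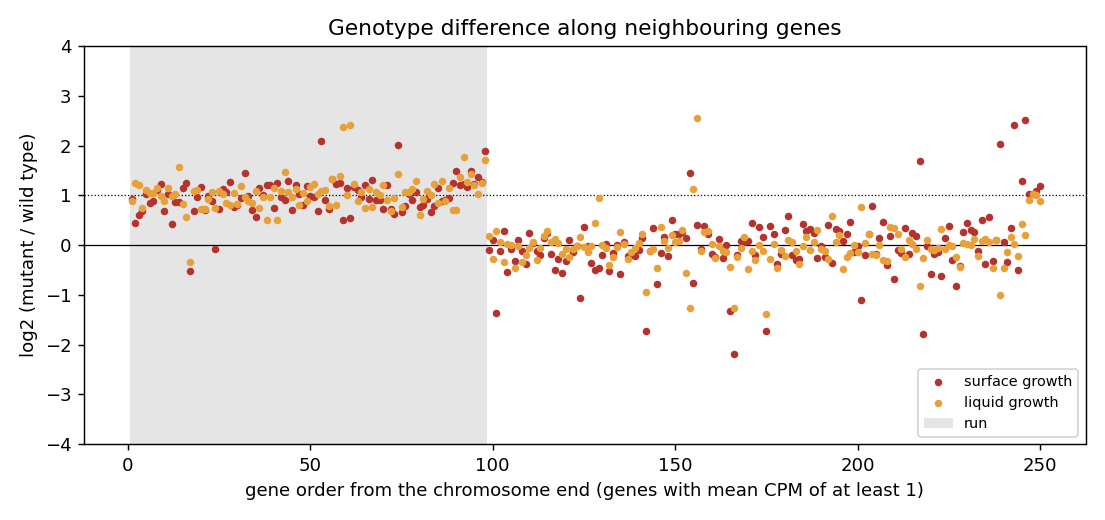
Log2 change of mutant against wild type for 250 genes in reference order along a chromosome, 1 point per gene and growth form, with the stretch of 98 genes shaded. Medians in the stretch are 0.96 in surface and 1.05 in liquid growth, and those of the next 40 genes -0.15 and -0.03.

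In wild type cells, the largest increases from surface to liquid growth among named genes that met the rule included genes of lysosomal proteases. The cysteine protease genes cprF (DDB_G0279185), cprE and cprG rose 16.9-, 7.94- and 3.42-fold (cprF from 30.2 ± 2.89 to 511 ± 63.3 CPM; SD, n = 6), the tripeptidyl peptidase family genes tpp1C and tpp1F 6.27- and 5.16-fold, the cathepsin B gene ctsB 6.14-fold, and the counting factor component cf45-1 3.97-fold. The cysteine protease gene cprA, named outside the rule for this comparison after its values were seen, fell from 68.2 to 40.8 CPM. Of 32 lysosomal enzyme genes 19 rose, 11 of them at least 2-fold, and 8 fell (adjusted p = 2.7e-11; adjusted p = 0.084 with an estimated correlation). Of 11 genes of the vacuolar proton pump, which acidifies endosomes, 9 rose and 0 fell, such as vatE (0.79), vatP (0.70) and vatG (0.69), with adjusted p = 4.5e-06 and adjusted p = 0.047 with an estimated correlation. Lower in liquid were cxgS (DDB_G0277839), the low-oxygen form of a cytochrome c oxidase subunit (10.8 ± 4.46 to 0.136 ± 0.051 CPM), alfA (12.7-fold), act19 (10.8-fold), dia2 (9.45-fold), the mitochondrial carrier gene mcfV (8.49-fold), stcC (7.58-fold), sigB (7.22-fold) and vwkA (7.16-fold). The normal-oxygen form cxgE rose 2.10-fold, from 84.0 ± 16.9 to 176 ± 10.3 CPM.

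Of 80 cytosolic ribosomal protein genes 79 rose and 0 fell in liquid in the wild type, with a median log2 change of 0.73 (0.35 under total-count scaling), including rps29 (1.99-fold) and rpl19 (1.98-fold). The adjusted p was 1.4e-20, and the adjusted p with an estimated correlation was 0.41. Of 35 nuclear genes of mitochondrial respiration 29 rose, such as cxfA (0.74; adjusted p of the list 7.2e-07, and adjusted p = 0.15 with an estimated correlation). Of 10 RNA interference genes 7 fell, led by the Argonaute gene agnB (-2.61) and agnC (-0.86), with adjusted p = 0.0041, adjusted p = 0.084 with an estimated correlation and adjusted p = 0.12 with total-count scaling. Of 37 polyketide synthase genes 25 fell, such as pks2 (-1.88; adjusted p = 0.029, adjusted p = 0.63 with an estimated correlation and adjusted p = 0.24 with total-count scaling). Adjusted over the list alone, 19 lysosomal enzyme genes rose and 8 fell, 9 and 0 proton pump genes, 80 and 0 ribosomal protein genes, 29 and 1 respiration genes, 2 and 7 RNA interference genes, and 2 and 25 polyketide synthase genes. DDB_G0288123 and DDB_G0291912 rose 31.4- and 8.57-fold, DDB_G0272386 and DDB_G0276097 fell 21.3- and 15.1-fold, and ai2a rose 3.23-fold. Of the genes the rule named in this comparison, stcC had the highest adjusted p (0.0018). In total 6743 genes passed, 3025 higher and 3718 lower in liquid, and 162 and 781 of these changed at least 2-fold (943 in all, and 265 when a mean CPM of at least 5 was required). Total-count scaling gave 880 higher and 7114 lower.

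In mutant cells 21 of 32 lysosomal enzyme genes rose in liquid growth. The largest increases among named genes that met the rule were 10.9-fold for cprF, 3.99-fold for cprE, 3.41-fold for tpp1F, 3.29-fold for ctsB, 3.23-fold for tpp1C, 3.03-fold for aplG, 2.90-fold for cf45-1 and 2.44-fold for uduF. Of the lysosomal enzyme genes 6 fell (adjusted p of the list = 5.5e-17), and of 11 proton pump genes 9 rose and 0 fell, such as vatC (0.63) and vatE (0.54; adjusted p = 1.3e-06). Both lists had an adjusted p of 0.017 with an estimated correlation. The largest decreases among named genes that met the rule were in act19 (12.4-fold), stcC (9.37-fold), the flavohemoglobin gene fhbB (7.69-fold), act21 (4.65-fold), warA (4.55-fold), cupF, cupC and cupI (4.31-, 4.28- and 3.92-fold). The stcC level in mutant surface cultures, 21.5 CPM, rested on replicate 6 with 88.6 CPM, and the mean without it was 8.10 CPM. Without that library the decrease of stcC was 3.53-fold (adjusted p = 0.0019).

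Of 32 actins 20 fell and 1 rose in liquid in the mutant, including act7 (-1.37) and act1 (-1.36), with adjusted p = 5.2e-09, and adjusted p = 0.37 with an estimated correlation. Of 20 genes on the substrate adhesion list 14 fell and 0 rose (adjusted p = 0.00012, and adjusted p = 0.63 with an estimated correlation). Among them were the integrin-like sibA (-0.65), and csbA (-1.05) and csbB (-0.82), which are also on the aggregation list. Of 27 secreted density and proliferation factors 17 fell, including ctnC (-1.86) and psiQ (-1.15), while cf45-1 (1.54) was among the 4 that rose (adjusted p = 0.0059; adjusted p = 0.71 with an estimated correlation). Adjusted over the list alone, 21 lysosomal enzyme genes rose and 6 fell, 9 and 0 proton pump genes, 1 and 20 actins, 0 and 14 adhesion genes, and 4 and 17 secreted factors. Among genes without a name, DDB_G0293604 and DDB_G0267306_RTE rose 52.4- and 21.9-fold, and DDB_G0289519 and DDB_G0288219 fell 26.2- and 16.9-fold. In total 4966 genes passed, 2453 higher and 2513 lower in liquid, and 165 and 241 of these changed at least 2-fold (406 in all, and 142 when a mean CPM of at least 5 was required). Total-count scaling gave 2868 higher and 1716 lower.

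The interaction asked whether the genotype difference depended on the growth form. Among named genes with a mean CPM of at least 10 in the highest group, the largest positive values, a mutant to wild type ratio higher in liquid than on the surface, were in alfA (DDB_G0274391; log2 3.91, SE 0.113), comD (3.27), cinC (3.21), dia2 (2.95) and mcfV (2.67). The dia2 gene stood at 19.6 ± 2.61 CPM in wild type surface cultures and at 2.55 ± 0.517, 2.05 ± 0.482 and 2.09 ± 0.296 CPM in mutant surface, wild type liquid and mutant liquid cultures (SD, n = 6). The largest negative values among them were in cupF (DDB_G0289813; -2.81), cupH (-2.67), cupC (-2.66), cupI (-2.66) and cupB (-2.45). Of 80 ribosomal protein genes 79 had a negative and 0 a positive interaction, with a median of -0.76 and examples rpl12 (-0.99) and rpl19 (-0.96), adjusted p = 2.1e-22, and adjusted p = 0.48 with an estimated correlation. Of 20 genes on the substrate adhesion list 15 were negative, with adjusted p = 2.3e-06, and adjusted p = 0.48 with an estimated correlation. The largest were csbA (-1.83) and csbB (-1.45), which are also on the aggregation list. The adhesion median was -0.42, and 0.03 under total-count scaling. Of 13 glycolysis and glycogen genes 11 were negative, such as pgkA (-0.86) and gpdA (-0.77), with adjusted p = 8.4e-05, and adjusted p = 0.48 with an estimated correlation. Adjusted over the list alone, 79 ribosomal protein genes were negative and 0 positive, 16 and 2 adhesion genes, and 11 and 0 glycolysis genes. In total 5531 genes passed, 2911 positive and 2620 negative, of which 710 and 176 were at least 2-fold (886 in all, and 230 when a mean CPM of at least 5 was required). Total-count scaling gave 7233 positive and 658 negative.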

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

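The genotype difference depended on the growth form in 5531 of 10116 genes, by the interaction test of edgeR. Genes with a positive interaction were alfA (log2 3.91), comD (3.27), cinC (3.21), dia2 (2.95) and mcfV (2.67). In alfA, comD, dia2 and mcfV the wild type surface cultures had the highest level, as dia2 shows with 19.6 CPM against 2.55 in mutant surface, 2.05 in wild type liquid and 2.09 in mutant liquid cultures. In cinC the mutant liquid cultures were highest (255 CPM) and the wild type liquid cultures lowest (27.4 CPM), with 126 and 127 CPM in wild type and mutant surface cultures. The negative interactions of cupF (-2.81), cupH (-2.67), cupC (-2.66), cupI (-2.66) and cupB (-2.45) went with a higher mutant level in surface growth and a lower one in liquid growth. Of 59 genes named in the pairwise comparisons, 49 passed the interaction test, as did 54.7% of all tested genes. The 59 were picked from the same libraries for large changes between groups that also enter the interaction, which favours passing.

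Of 31 lists, 10 passed for the interaction at the preset correlation, and 0 passed with an estimated correlation, where the adjusted p of these 10 ran from 0.48 to 0.67. Lists with a negative direction were cytosolic ribosomal proteins (adjusted p = 2.07e-22), actin-binding and motility (4.17e-08), substrate adhesion (2.29e-06), mitochondrial respiration (3.99e-05), glycolysis and glycogen (8.37e-05), ribosome biogenesis (0.000429), actins (0.0249), aminoacyl-tRNA synthetases (0.0280) and DNA replication (0.0408). Transposable elements had a positive direction (0.0391). With total-count scaling this call was lost and the direction of the test turned negative (adjusted p = 0.0957), while the list's median stayed positive (0.26 to 0.69). Total-count scaling moved the median interaction of all genes from 0.06 to 0.50, and this shift alone brings most list medians near or over 0. They became positive for substrate adhesion (-0.42 to 0.03), actins (-0.31 to 0.14), DNA replication (-0.22 to 0.22), ribosome biogenesis (-0.27 to 0.17), mitochondrial respiration (-0.38 to 0.06) and aminoacyl-tRNA synthetases (-0.16 to 0.28), and stayed negative for ribosomal proteins (-0.76 to -0.31), actin-binding and motility (-0.46 to -0.02) and glycolysis and glycogen (-0.49 to -0.04). With total-count scaling the calls of aminoacyl-tRNA synthetases (adjusted p = 0.736) and DNA replication (0.826) were lost and the direction of their tests turned positive, although the medians of all 9 lists lay below that of all genes.

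Other groupings of the same libraries were fitted to see how many genes they call, with 40 drawn, the real one included, out of 462 for each pair of groups; the test for the interaction was chosen after its count was seen. In each of the 4 pairwise comparisons 1 of the 40, the real one, called as many genes. Every other grouping mixes libraries of the compared groups, so a real difference widens the spread within it and can lower its count. The counts of the other groupings therefore do not measure chance alone. A culture or harvest batch that coincides with a group, which the labels do not record, cannot be told apart by these groupings. The real grouping, fitted with the compared groups alone, and the highest other called 6517 and 0 genes for mutant against wild type in surface growth, 3787 and 432 in liquid growth, 6587 and 2544 for liquid against surface growth in the wild type, and 5020 and 0 in the mutant. For the interaction, the effects of genotype and growth were kept and the residuals of the model without interaction were exchanged among the libraries, with limma on log2 CPM. Of 100 groupings 1, the real one, called as many genes (5589, against 1775 in the highest other). The exchanged residuals still hold any real interaction, which widens the spread of the drawn groupings, so their counts do not measure chance alone.

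A library lay apart from the other 5 of its group in 12 of 248 sets of values (4.84%), where chance alone gives about 1 in 20; the measure is the gap to the nearest library divided by the range, held against Dixon's critical value for 6 samples. Mutant surface replicate 4 had 56.2 M counts against 79.0 to 90.5 in the others (gap share 0.666). Wild type surface replicate 2 had the lowest TMM factor of its group (1.05; 0.665), the highest share of ribosomal protein counts (22.3%; 0.697) and the highest cprF (0.701) and tpp1F (0.639) levels. Wild type surface replicate 1 had the highest celB (0.722) and vwkA (0.630) levels and the lowest level of DDB_G0288219 (0.843). Wild type liquid replicate 3 had the highest sodC (0.701) and act19 (0.649) levels, replicate 1 the lowest warA level (0.695) and replicate 5 the lowest level of DDB_G0288219 (0.670).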

How the results depend on the processing

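Scaling by total counts, leaving out stretches of neighbouring genes and leaving out single libraries were chosen after the data were seen. The number of genes called in each of the 5 comparisons stayed within 1.5 times its value under every alternative run. Their split by direction did not hold under total-count scaling. It went from 2929 higher and 3295 lower to 1023 and 6352 in surface genotype. For the interaction it went from 2911 positive and 2620 negative to 7233 and 658. The 141 results for named genes kept their direction and passed in all 1834 alternative values. Those genes were picked from the same libraries for large differences past the threshold, so their agreement was largely set by that choice. The number called and changed at least 2-fold was lower when a mean CPM of at least 5 was required (6208 genes tested): 194 against 686, 168 against 540, 265 against 943, 142 against 406 and 230 against 886, in the order surface genotype, liquid genotype, wild type growth, mutant growth and interaction. In that order 70.0%, 68.9%, 72.7%, 65.0% and 75.1% of the genes called and changed at least 2-fold had a mean CPM under 5. Leaving out a single library, or replicate 1 of every group, gave 5821 to 6333, 4028 to 4104, 6519 to 6758, 4571 to 4671 and 5279 to 5695 genes.

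With the replicate number as a block the counts were 6198, 4166, 6759, 4927 and 5529, against 6224, 4141, 6743, 4966 and 5531. The labels state no pairing, and deviations of libraries with the same number correlated at -0.23 to 0.31 over 36 pairs (median -0.01), so the numbers were not used as pairs. The 6 pairs of replicate 1 stood apart: 5 of them were over 0.1 and 5 had their best match in their own number, and the lowest was 0.08, while the highest of any other number was 0.07. The libraries numbered 1 thus deviated together across groups, in a way the labels do not record; without them the counts were 5904, 4104, 6677, 4571 and 5465.

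Of 155 list tests 48 passed; 3 passed with an estimated correlation, 119 with fry, which asks only whether the members move one way on balance, and 50 with total-count scaling, of which 38 were shared. The direction reversed under total-count scaling for aminoacyl-tRNA synthetases in wild type growth (adjusted p = 0.883) and in the interaction (0.736), for DNA replication in the interaction (0.826) and for transposable elements in the interaction (0.0957); the cause was not tested. A further 6 calls kept their direction and no longer passed: transposable elements (0.237) and DNA replication (0.0892) in surface genotype, and polyketide synthases (0.242), transposable elements (0.133), RNA interference (0.117) and actin-binding and motility (0.117) in wild type growth. A search for a sequence motif downstream of stop codons, with its alternatives, was not run because no genome sequence was used here.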

Other observations

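In wild type cells, 10 of 12 histone genes rose and 2 fell in liquid against surface growth (adjusted p = 0.029; adjusted p = 0.41 with an estimated correlation), and 17 of 26 nuclear genes of mitochondrial ribosomal proteins rose while 0 fell (adjusted p = 0.0018; adjusted p = 0.24 with an estimated correlation). Adjusted over the list alone, 10 and 2 histone genes and 17 and 0 mitochondrial ribosomal protein genes passed. Of 198 transposable elements 124 fell and 20 rose in liquid growth in the wild type (adjusted p = 6.2e-05; adjusted p = 0.15 with an estimated correlation and adjusted p = 0.13 with total-count scaling), and 65 fell and 17 rose in the mutant (adjusted p = 0.029; adjusted p = 0.63 with an estimated correlation). Of these elements 125 fell and 20 rose in the wild type, and 62 fell and 16 rose in the mutant, adjusted over the list alone. Of 37 proteasome genes 26 rose and 3 fell in liquid growth in the wild type (adjusted p = 0.00023; adjusted p = 0.15 with an estimated correlation). Their median there was 0.28, and -0.08 under total-count scaling. In the mutant 26 rose and 0 fell (adjusted p = 0.00068; adjusted p = 0.34 with an estimated correlation). The proteasome counts adjusted over the list alone were 26 and 3 in the wild type and 28 and 0 in the mutant. In total 12 lists passed in no comparison at the preset correlation, with the lowest adjusted p of ABC transporters (0.0581), lipid metabolism (0.0646), autophagy (0.0902), prestalk markers (0.131), prespore and spore markers (0.166), aggregation and cAMP signalling (0.177), mRNA decay (0.205), small GTPases (0.236), the endocytic pathway (0.262), sexual cycle markers (0.367), oxidative stress (0.539) and oxygen-linked genes (0.546).

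In the patterns below, the tests on neighbouring genes and on nearly absent genes, with their window, limits and bounds, were chosen after the values were seen, and the tests on shared controls, low abundance and genomic DNA before. A stretch of 98 neighbouring genes from a chromosome end was higher in the mutant in both growth forms, with 96 of 98 genes passing in both. To look for a scaling difference between libraries, the next 40 genes were taken, whose higher median log2 change was -0.029. The end of the stretch had been set where a running median over 21 genes fell under 0.5. A low value after it was thus largely fixed in advance and cannot decide on scaling. Chance order of genes is argued against by 0 of 1000 shuffled orders with a stretch as long (longest 4). A second copy of the region in the mutant line is a candidate explanation: the median farthest from 1 on the log2 scale was 1.05, within the bounds set for it. A further 11 genes, from DDB_G0271970 to DDB_G0272038, had medians of 1.09 in surface and 0.89 in liquid growth. They were uneven at the start, with 2.40 and 0.03 in DDB_G0271970, -0.50 and -0.21 in rpb10, 1.29 and 0.43 in rpl32 and 2.51 and 0.19 in rabR. Most later ones lay nearer 1, with 1.02 and 0.90 in DDB_G0272054, 1.03 and 1.04 in DDB_G0271982, 1.09 and 1.01 in gefG and 1.18 and 0.89 in rab5A. The last were DDB_G0272056 (1.30 and 0.94), DDB_G0271986 (0.41 and 0.99) and rgfA (0.93 and 0.84). All but rpl32 are named outside the rule, after their values were seen. The 11 genes are not counted toward a second copy. Copy number was not measured, and a shared regulation of the region by ttpA stays open as an untested biological explanation.

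Transcripts of 10 genes were at least 16-fold lower in the mutant in both growth forms, namely prsB, cprA, zfaA, DDB_G0290967, DDB_G0290971, DDB_G0267194, DDB_G0267196, DDB_G0267198, DDB_G0282919_TE and DDB_G0292272_TE, and 1 gene, ponC4, was higher by as much (6.52 against 0.286 CPM in surface growth); those of them that the rule for named genes does not take were chosen after their values were seen. Their median level in the mutant was 1.15% of wild type in surface growth, or 1.47% with zfaA, which had 0 counts there, set to a floor of 3 counts over the group (at least 69.1-fold lower); cprA stood at 1.24% of wild type in liquid growth. Low depth is argued against by a median of 10542 counts per gene over the wild type libraries. Of the 10 genes, 6 formed 4 neighbouring pairs (zfaA, cprA and DDB_G0290971, and DDB_G0267194, DDB_G0267196 and DDB_G0267198), where 1000 shuffled gene orders gave at most 1, so loss from the mutant line may account for these 6. The pairs do not cover prsB, DDB_G0290967 and both transposable elements. Among tested genes only DDB_G0290969 (log2 -7.25 in surface and -3.63 in liquid growth, mean CPM 0.069) lay between DDB_G0290967 and zfaA. Beside prsB, DDB_G0272484 (-3.45 and -4.86) and DDB_G0272482 (-1.61 and -4.04, mean CPM 0.190) were lower too. These neighbours are named outside the rule, after their values were seen. Tested neighbours of the transposable elements were not lower by as much. Loss, if it took place, may thus not be limited to the 6 genes. Gene loss was not measured, and an effect of ttpA on all 10 transcripts stays open and untested.

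Mutant surface cultures differed from wild type surface cultures in the direction in which wild type liquid cultures did, and both comparisons use the same wild type surface libraries: 2007 genes were higher in both (876 for independent lists) and 2229 lower in both (1211), and the log2 changes had a Pearson correlation of 0.60 and a covariance of 0.228 across genes, which are not independent replicates. The shared libraries are argued against as the whole source by a mean covariance of 0.223 (0.217 to 0.228) with separate sets of controls in 20 splits, against a mean of 0.00668 and a highest value of 0.00725 in 20 simulations of unchanged groups, where r was 0.47. Background in genes of low abundance is argued against as the whole source by r = 0.49 (0.46 to 0.51) with separate controls. That value covers the 2296 genes with a mean CPM of at least 50 and cannot decide on genes of lower abundance. A mean CPM under 5 was found in 70.0% of genes called and changed at least 2-fold in surface genotype, and in 72.7% in wild type growth. Genomic DNA in the wild type surface libraries cannot be told apart for genes of low abundance, because the 10th percentile of CPM per kilobase was 0 in every group and the planned ratio had no value. Wild type surface cultures grown or harvested apart from the others, which the labels do not record, and a change in the mutant toward the state of liquid growth both stay open and untested.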
